A study of Mus musculus with 13 samples.

How the data were processed

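Regulatory T cells were profiled on Affymetrix Mouse Gene 1.0 ST arrays, with 13 arrays in 7 groups. Per the labels, CD4 and T-cell receptor beta positive cells with the top 50% of CD25 staining were sorted from male mice, with a Foxp3 purity over 99%. Sorting took 2 rounds for spleen and 3 for bone marrow. Per the labels, markers of B cells, CD8 T cells, γδ T cells, myeloid cells, NK cells and erythroid cells were excluded in the sort. The mice were 9 weeks old, except bone marrow replicate 2 at 8 weeks. The design text speaks of 2 biological replicates per condition, and CBA has 1 array here.

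The deposited values are intensities on a linear scale, between 4.23 and 18672, for 24922 probe sets. They were made with Affymetrix Power Tools and RMA, per the submitters' processing notes, which give no version. The genome build is not given in the sources used here. The deposited intensities were converted to log2 here, with no pseudocount added. Of the probe sets, 21425 had 1 gene symbol, 1399 had several and 2098 had none. Probe sets with 1 symbol were used, symbols were updated by Entrez identifier (21347 matched), and 19752 symbols remained, 921 of them with several probe sets, of which the one with the highest mean was kept. A gene was tested when its highest group mean reached the median of all values (log2 6.376, an intensity of 83), which left 11244 genes. Median intensities of the arrays lay between 77.2 and 90. No background level was measured, so folds against a group with very low intensities are uncertain in size. Probe sequences were not compared with the genomes of the strains, so a strain difference in signal may not be one in expression.

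A linear model with 7 group means was fitted to all 13 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (6 residual and 6.95 prior degrees of freedom). The lone CBA array was assumed to vary like the other groups. The p-values measure the spread between these samples. Benjamini-Hochberg adjustment was made within each comparison, and a gene passed at an adjusted p below 0.05. Comparisons were each strain against the mean of the other 4 strains, an F test over the 5 strains, NZW bone marrow against tissue-set NZW spleen, and tissue-set against strain-set NZW spleen. Tissue-set NZW spleen was also set against the other 4 strains, with a simulation of the arrays that both comparisons share. The sets were defined from the word order of the titles.

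The comparisons, 22 gene lists and alternatives were fixed before the data were examined. The lists covered genes high and low in regulatory T cells, interleukin-2 and STAT5 targets, Foxp3 regulation and stability, the effector and resting states, helper T cells, the interferon response, the cell cycle, the MHC region, T-cell receptor beta segments and signalling, coinhibitory and trafficking receptors, apoptosis, and immediate-early and heat-shock genes. Marker lists covered B cells, plasma cells, myeloid cells, neutrophils and marrow progenitors, erythroid cells and platelets, and NK, CD8 and γδ T cells. Of the list genes, 520 had a symbol on the array. Lists with 3 or more tested members were tested with camera of limma at a correlation of 0.01 and again with an estimated correlation, and p was adjusted over lists within a comparison.

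Genes named in the text were chosen by a rule written in advance. They are the 10 largest rises and the 10 largest falls among genes that passed and whose arrays did not overlap, up to 4 members with the smallest p in each list, and Foxp3, Il2ra, Ikzf2, Ctla4, Il7r, Trbc1, Trbc2 and Cxcr4 where measured. Predicted and unnamed genes were passed over. Trbc1 and Trbc2 were not measured, which left 6 of these genes. Other genes are said to have been chosen after their values were seen.

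The code was tested on simulated data with the real groups and 11244 genes. For NZW against the other strains, 22% of changes of 0.5 on the log2 scale and 100% of changes of 1 were called, with 8 false calls among 169. For bone marrow against spleen these shares were 6% and 88%, with 6 false calls among 153, and for CBA 6% and 72%, with 6 false calls among 143. A shifted list was called and 0 of 20 other lists were, with either correlation. The simulated genes varied independently, so this run cannot show how often lists of correlated genes would be called falsely.

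Alternatives were no expression filter, all probe sets, the mean of a gene's probe sets, an added constant of 16, a floor at log2 7, a 1.5-fold threshold, arrays of 1 set only, limma array weights (statmod 1.5.0), a variance trend with robust moderation, equal weights for the 7 arrays of the other strains, another quantile normalization, median centring, the replicate number as a block, pooling of the 4 NZW spleen arrays, and leaving out each array in turn. Strain-set spleen as the reference for bone marrow, and leaving out B6 replicate 2 with NOD replicate 1, were added after the data were seen.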

Results

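Regulatory T cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. Gene expression was measured in these cells, sorted from male mice of 5 inbred strains, on 13 Affymetrix Mouse Gene 1.0 ST arrays. Spleen cells of the strains B6 (2 arrays), Balb (2), CBA (1), NOD (2) and NZW (2) formed a strain set of 9 arrays. A tissue set of 4 arrays, whose titles followed another word order, held NZW bone marrow (2 arrays) and NZW spleen (2 arrays). The division into these sets rests on the titles alone. Median intensities lay between 77.2 and 90, and 11244 genes were tested. The number of arrays limits the precision of every value, and differences are given on the log2 scale ± the standard error (SE) of the model fitted to all 13 arrays.

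No strain passed the limma test for Foxp3, Il2ra, Ikzf2 or Ctla4. Foxp3 in NZW spleen stood 0.12 ± 0.18 above the mean of the other 4 strains, Il2ra, which encodes CD25, 0.01 ± 0.13, Ikzf2 −0.01 ± 0.16 and Ctla4 −0.10 ± 0.14, with limma adjusted p = 1 for each after Benjamini-Hochberg adjustment. The largest differences of these genes were Foxp3 in B6 (−0.43 ± 0.18, limma adjusted p = 0.337) and Ctla4 in CBA (0.56 ± 0.18, limma adjusted p = 0.503). The 2 B6 arrays disagreed on Foxp3, with an SD of 0.596 against 0.064 over the 7 arrays of the other strains. The 6 genes fixed for every comparison were measured in all 7 groups. Correlations across genes between each array and its nearest neighbour were 0.9742 or more on 12 arrays. B6 replicate 2 stood apart, with a highest correlation of 0.9319 and 756 genes more than 2-fold away from B6 replicate 1, where the other pairs of replicates had 18 to 57 such genes.

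The first question, given by the series title, was which genes differ among strains. Differences here are in array signal, since the match of the probes to each strain's sequence was not checked. The moderated F test of limma called 307 of 11244 genes (2.73%) across the 5 strains of the strain set, and 1224 genes had an unadjusted p below 0.05. The median range between the highest and the lowest strain among called genes was 2.79-fold, the widest was 31.3-fold, and 283 genes spanned at least 2-fold. The widest range belonged to Cyth1, at a log2 level of 5.16 in Balb and 10.12 in NZW (limma adjusted p = 3.98e-08). Ifitm2 ranged from 8.34 in B6 to 12.83 in NZW (limma adjusted p = 2.38e-08), Trim30d from 4.10 in CBA to 8.20 in B6, and Nkg7 from 6.45 in NZW to 10.23 in CBA. Of the called genes, 74 were highest in NZW, 69 in CBA, 64 in NOD, 57 in B6 and 43 in Balb. Pairs of strains with 2 arrays each differed in 115 genes (B6 and Balb) to 180 genes (B6 and NOD). Pairs with CBA, which had 1 array, gave 38 to 83. The count rose to 571 without B6 replicate 2 and to 2665 without B6 replicate 1.

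In NZW spleen, genes of the interferon-induced transmembrane family, whose products restrict the entry of viruses, stood far above the other strains. Ifitm2 was 19.8-fold higher, at 12.83 ± 0.03 (SD, n = 2) against a mean of 8.52 ± 0.14 (SD, n = 7), a difference of 4.30 ± 0.13 (limma adjusted p = 8.64e-10). Ifitm1 rose by 3.60 ± 0.18 and Ifitm3 by 2.96 ± 0.17. Among cytotoxic granule genes, Gzma, which encodes granzyme A, rose by 2.28 ± 0.19 (limma adjusted p = 1.98e-05), while Nkg7 fell by 2.96 ± 0.22 (limma adjusted p = 8.66e-06). Both replicates lay outside the range of the other 7 arrays for each of these genes.

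**Figure D1:**
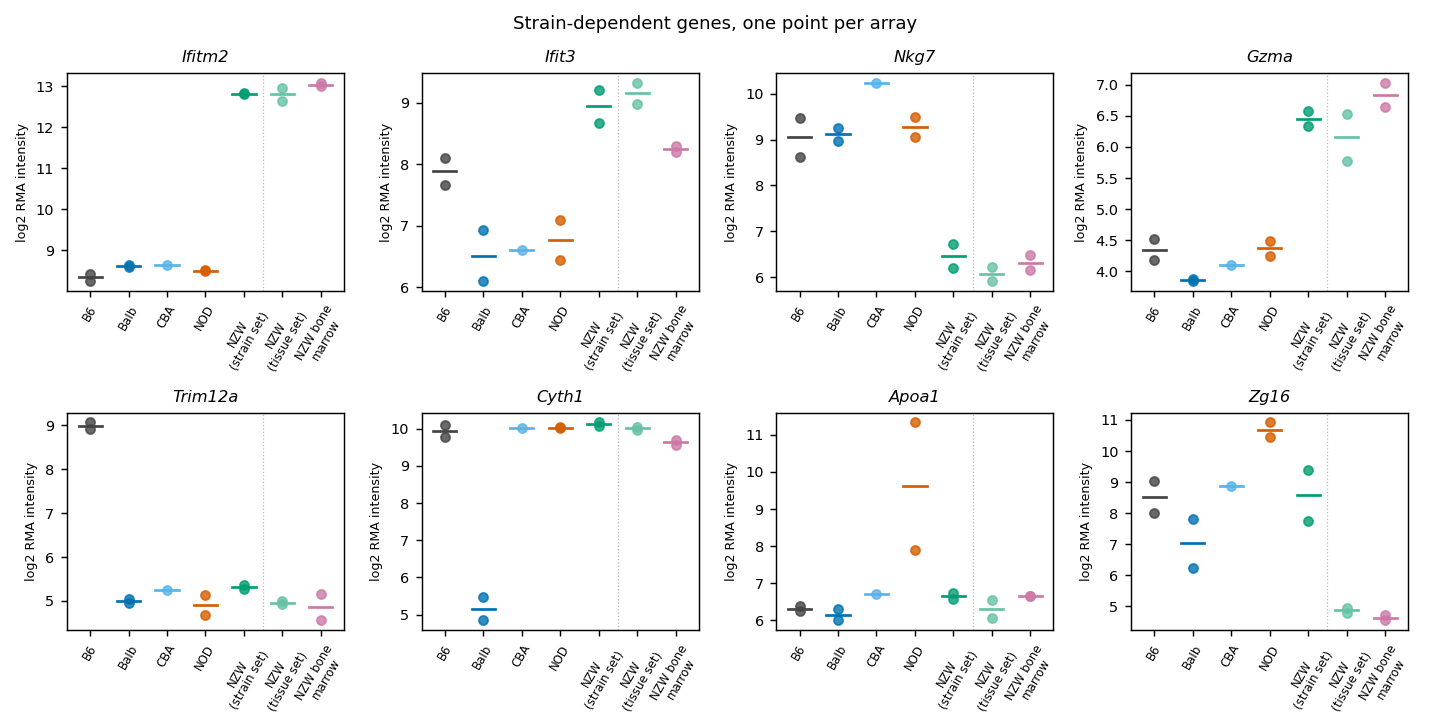
Log2 RMA intensity of 8 genes on each of the 13 arrays. Each point is 1 array, horizontal lines are group means, and a dotted line parts the strain set (left) from the tissue set (right). Ifitm2 lies at 12.83 in strain-set NZW spleen and at 8.34 in B6 spleen, Cyth1 is low in Balb alone, and Apoa1 differs between the 2 NOD arrays.

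Other genes with the largest rises in NZW were Btbd3 (3.13 ± 0.14), Akr1c18, a steroid dehydrogenase (2.84 ± 0.19), Ifi213 (2.50 ± 0.20), Dhdh (2.33 ± 0.17), Ifit3 (2.00 ± 0.24) and Slc15a2, a peptide transporter (2.00 ± 0.38). The largest falls after Nkg7 included the glutathione S-transferase genes Gstp3 (−2.05 ± 0.14) and Mgst2 (−1.94 ± 0.15). Klrb1f (−1.88 ± 0.16), Churc1 (−1.76 ± 0.22), Rin2 (−1.30 ± 0.14), Arhgap20 (−1.29 ± 0.14), Cst7, an inhibitor of cathepsins (−1.23 ± 0.16), Rasgrf2 (−1.20 ± 0.13) and Pglyrp1 (−1.12 ± 0.16) followed. For Akr1c18, Arhgap20 and Klrb1f the NZW spleen arrays of the tissue set gave another size of difference, and for Klrb1f that difference was −0.25 and did not pass. B6 was nearly as high for Ifi213 (9.65 against 9.99 in NZW) and NOD nearly as low for Klrb1f (5.78 against 5.26).

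The interferon-response list, fixed before the data were examined and holding no Ifitm gene, stood higher in NZW. Of 40 members tested, 9 rose, none fell and 31 did not pass, and 38 had a positive difference, with a median of 0.466. Adjusted over the list alone, 22 rose. Oasl2 (1.81 ± 0.14) and Oas2 (1.53 ± 0.14), of the family of antiviral oligoadenylate synthetases, and Rsad2, which encodes viperin (1.65 ± 0.20), rose together with Ifit3. The camera test of limma gave an adjusted p of 6.45e-27, and adjusted p = 0.433 with an estimated correlation. NZW stood above each strain in turn, with list medians of 0.413 against B6, 0.312 against Balb, 0.556 against CBA and 0.599 against NOD.

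Of 32 cell-cycle genes, 1 rose (Ect2, 1.06 ± 0.13) and none fell, with 5 higher adjusted over the list alone, a median of 0.203 and a camera adjusted p of 1.76e-06 (adjusted p = 0.994 with an estimated correlation). Relative to the mean of all arrays, the cell-cycle median lay at 0.202 and 0.455 on the strain-set NZW arrays. On the tissue-set NZW spleen arrays it lay at −0.32 and −0.382, below every array of the other strains (lowest −0.134, B6 replicate 2). The rise of this list was thus limited to the strain-set NZW arrays. Of 42 genes known to be high in regulatory T cells, Gpr15, a homing receptor, rose (1.12 ± 0.19) and Cst7 fell, with 1 higher and 4 lower adjusted over the list alone. The median of that list was −0.101 and its camera adjusted p 0.000302 (adjusted p = 0.994 with an estimated correlation). Of 5 B-cell markers tested, Cd74, the invariant chain of MHC class II, rose (1.14 ± 0.20), also when adjusted over the list alone, with a list median of 0.279 and a camera adjusted p of 0.00886 (adjusted p = 0.433 with an estimated correlation). That median was 0.169 after another quantile normalization and 0.176 after median centring. That call was lost without NZW strain-set replicate 2 (camera adjusted p = 0.355) and with no filter (camera adjusted p = 0.298). Single members of other lists that passed were Nsg2 (1.66 ± 0.16), Il18r1, a receptor for interleukin-18 (0.96 ± 0.16), Anxa2 (0.88 ± 0.19), H2-Oa (−0.88 ± 0.14) and the heat-shock gene Hsph1 (0.73 ± 0.16). NZW was not the highest strain for Nsg2 (B6 9.29), Il18r1 (NOD 9.24) or Cd74 (B6 8.46). The remaining 17 lists gave camera adjusted p values of 0.498 to 0.994.

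In total, 140 genes differed between NZW and the mean of the other 4 strains, 88 higher and 52 lower, and 760 had an unadjusted p below 0.05. Left-out arrays moved this count to 58 without NZW strain-set replicate 1, 50 without NZW strain-set replicate 2, 330 without B6 replicate 1 and 249 without B6 replicate 2. Without B6 replicate 2 and NOD replicate 1, an alternative chosen after the data were seen, it was 225.

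The NZW spleen arrays of the tissue set gave a second measurement of the same strain against the same 7 arrays of other strains. Of the 140 genes, 137 (97.9%) kept their sign and 110 passed again in the same direction, 70 higher and 40 lower. Independent lists of these sizes would share 1.84 higher and 1.31 lower genes. The tissue set called 518 genes, 235 higher and 283 lower. Unchanged groups were simulated 100 times against the shared arrays, with the same spread on every array and no differences among the other strains. On average 72.7% of the top genes kept their sign, and the mean number called in both rounded to 0. The correlation of the differences across genes, which are not independent replicates, was 0.572 against 0.239 in the simulation, and the covariance 0.0449 against 0.0071. Real differences among the other strains shift both comparisons alike. The simulated values and the overlap of independent lists may therefore understate the agreement that shared arrays alone would give. With the other strains split so that no array was shared, 85.7% of 154 genes kept their sign with B6 and Balb used first, and 91.1% of 123 genes with CBA and NOD used first. Of these genes, 80 and 77 passed again in the same direction. The correlations of the differences were then 0.292 and 0.405, lower than with shared arrays. In the tissue-set arrays, 37 of 40 interferon-response genes lay above 0, with a median of 0.398, and 12 rose. The higher cell-cycle list of strain-set NZW was not repeated there. Its median lay at −0.32 and −0.382 from the mean of all arrays, below every array of the other strains.

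In B6 spleen, Trim12a and Trim30d, of the tripartite-motif family, were 14.7-fold and 9.62-fold higher than the mean of the other strains (3.87 ± 0.17 and 3.27 ± 0.19, limma adjusted p = 9.47e-08 and 5.32e-07). Apobec3, a cytidine deaminase that restricts retroviruses, rose by 2.16 ± 0.12 and Naip5, which senses bacterial flagellin, by 1.41 ± 0.25. The T-cell receptor alpha segment Trav12-2 rose by 2.95 ± 0.16 (limma adjusted p = 4.15e-07).

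Other rises in B6 were Gsta4 (2.87 ± 0.14), Rab6b (2.23 ± 0.26), Prrg4 (1.46 ± 0.16), Akr1e1 (1.30 ± 0.18) and Mtmr7 (1.29 ± 0.15). The largest falls were Pianp (−1.76 ± 0.18), Cpne4 (−1.55 ± 0.14), Ifitm2 (−1.31 ± 0.13), Atp9a (−1.29 ± 0.26), Ntn4 (−1.28 ± 0.12), Dnah8 (−1.21 ± 0.16), Inppl1 (−1.17 ± 0.23), Scg5 (−1.14 ± 0.14), Gnb4 (−1.14 ± 0.19) and the histone gene H2bc3 (−1.13 ± 0.13). The mean of the other strains for Ifitm2 includes the high NZW value, and NOD was nearly as low as B6 for H2bc3 (8.79 against 8.54). Without B6 replicate 2, Atp9a (−0.69), Inppl1 (−0.58), Gnb4 (−0.87), Tgfbr3 (−0.56), Dapl1 (1.11) and Slc16a5 (−0.46) were smaller and no longer passed. Naip5 (1.33), S100a4 (−0.68), Il18r1 (−0.79) and Oasl2 (0.74) kept about their size there but, with 1 array fewer, no longer passed.

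Of 32 effector regulatory T-cell genes in B6, none rose and 3 fell, namely the chemokine receptor Cxcr6 (−0.89 ± 0.15), Lgals3 (−0.78 ± 0.14) and S100a4 (−0.71 ± 0.15), with 6 lower adjusted over the list alone and a camera adjusted p of 0.0812 (adjusted p = 0.89 with an estimated correlation). Of 17 resting-state genes, Dapl1 rose (1.64 ± 0.33) and Slc16a5 fell (−0.65 ± 0.15), with 1 higher and 3 lower adjusted over the list alone, and the camera adjusted p was 0.567 (adjusted p = 0.89 with an estimated correlation). Of 18 genes known to be low in regulatory T cells, Nsg2 (1.71 ± 0.16) and Dapl1 rose while Amigo2 (−0.72 ± 0.13) and Tgfbr3 (−0.88 ± 0.17) fell, with 2 higher and 3 lower adjusted over the list alone and a camera adjusted p of 0.731 (adjusted p = 0.89 with an estimated correlation). Lad1 (1.01 ± 0.18), Cst7 (0.89 ± 0.16), Oasl2 (0.80 ± 0.14) and Cd74 (1.46 ± 0.20) rose and Il18r1 fell (−0.78 ± 0.16). B6 was not the extreme strain for Lad1 (8.14, Balb 8.48), Oasl2 (7.82, NZW 8.62) or Il18r1 (7.62, Balb 7.48), and was close to NZW for Nsg2 (9.29, NZW 9.25) and Cd74 (8.46, NZW 8.20), to CBA for Cst7 (9.96, CBA 9.68) and to NOD for S100a4 (7.90, NOD 8.02). None of the 21 lists tested by camera passed at an adjusted p of 0.05, and the lowest adjusted p was 0.0812. Without B6 replicate 2 there were 6 such lists and without Balb replicate 1 there were 4.

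In total, 149 genes differed in B6, 73 higher and 76 lower, and 1549 had an unadjusted p below 0.05. The count was 3513 without B6 replicate 1, 96 without Balb replicate 1, 99 without Balb replicate 2 and 95 without NZW strain-set replicate 2. With limma array weights, which lower the weight of arrays that vary widely about their own group mean, it was 26. Arrays of a pair lie equally far from their mean, so these weights cannot single out B6 replicate 2 from B6 replicate 1.

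Balb spleen lacked most of the signal of a pair of genes that were high in every other group. Cyth1, which encodes the guanine nucleotide exchange factor cytohesin-1, was 29.2-fold lower, at 5.16 ± 0.43 (SD, n = 2) against 10.02 ± 0.12 (SD, n = 7), a difference of −4.87 ± 0.16 (limma adjusted p = 2.72e-09). Coro2a, of the actin-binding coronins, was 14.5-fold lower (−3.86 ± 0.14, limma adjusted p = 2.79e-09). Dnah17, an axonemal dynein gene that neighbours Cyth1 among the tested genes, was 8.46-fold higher (3.08 ± 0.16, limma adjusted p = 1.75e-07). Il7r, the receptor for interleukin-7, fell by 0.93 ± 0.15 (limma adjusted p = 0.00696).

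Further rises in Balb were the guanylate-binding protein Gbp2b (1.94 ± 0.15), Rhob (1.57 ± 0.13), Smc6 (2.82-fold higher), Dnah8 (1.37 ± 0.16), H2-Ob (1.17 ± 0.17), Dapk1 (1.16 ± 0.15), Ckb (1.08 ± 0.17), Slc16a5 (1.05 ± 0.15) and Ifnz (1.05 ± 0.14). Further falls were Nsg2 (−2.37 ± 0.16), Tex35 (−2.35 ± 0.14), Oasl2 (−1.91 ± 0.14), Cd74 (−1.70 ± 0.20), Ms4a6d (−1.66 ± 0.17), Adh1 (−1.47 ± 0.17), Arl2bp (−1.46 ± 0.15) and Ly6e (−1.39 ± 0.14). Lad1 (1.45 ± 0.18), Gbp4 (0.80 ± 0.15), Amigo2 (0.80 ± 0.13) and Eomes (0.70 ± 0.13) rose, while Crip1 (−1.07 ± 0.14), Il18r1 (−0.96 ± 0.16) and Gzma (−0.96 ± 0.19) fell, and for Gzma the mean of the other strains includes the high NZW value. B6 lay close to Balb for Tex35 (5.81 against 5.44), Lad1 (8.14 against 8.48) and Il18r1 (7.62 against 7.48), CBA for Cd74 (6.35 against 5.93) and Dapk1 (7.63 against 7.94), and NOD for Ms4a6d (5.25 against 4.75).

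Markers of other cell types were the only lists that passed in Balb. Of 5 B-cell markers, Cd74 fell and none rose, with 4 lower adjusted over the list alone, a median of −0.418 and a camera adjusted p of 8.86e-07 (adjusted p = 0.0843 with an estimated correlation). Of 5 myeloid markers, none passed singly or adjusted over the list alone, all lay below 0 with a median of −0.297, and the camera adjusted p was 0.00781 (adjusted p = 0.854 with an estimated correlation). The 19 other lists had camera adjusted p values of 0.0663 to 0.94, and 4 lists passed without either Balb array. In total, 81 genes differed in Balb, 29 higher and 52 lower, and 863 had an unadjusted p below 0.05. The count was 30 without Balb replicate 1, 28 without Balb replicate 2, 482 without B6 replicate 1 and 163 without B6 replicate 2. It was 150 without B6 replicate 2 and NOD replicate 1.

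CBA was represented by 1 array, whose spread was taken from the other groups, so these differences have no replicate check within the strain. Tex35 was 4.83-fold higher than the mean of the other strains (2.27 ± 0.19, limma adjusted p = 0.000239), Litaf 3.64-fold (1.87 ± 0.18, limma adjusted p = 0.000818) and Nkg7 3.38-fold (1.76 ± 0.29, limma adjusted p = 0.0228). The mean against which Nkg7 was set includes the low NZW arrays, and Tex35 was also high in NOD (8.32 against 9.13 in CBA). The interferon-inducible genes Gbp8 (−1.91 ± 0.26), Ifi213 (−1.89 ± 0.26) and Slfn8 (−1.78 ± 0.22) fell, as did Cd72 (−1.88 ± 0.26) and Trim30d (−1.86 ± 0.25). The mean of the other strains for Trim30d includes the high B6 value (8.20), with Balb at 4.40 and CBA at 4.10, and that for Ifi213 the high NZW and B6 values, with NOD at 6.78 and CBA at 6.48. Cd72 was also low in NOD (5.83 against 5.44).

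Further rises in CBA were Prune2 (1.73 ± 0.23), Lrrn4 (1.70 ± 0.18), Plppr1 (1.60 ± 0.24), the fatty-acid binding gene Fabp5 (1.60 ± 0.26), Cryab (1.40 ± 0.23), the protease gene Ctse (1.37 ± 0.24) and Syt14 (1.34 ± 0.24). Further falls were Sh3bgrl2 (−1.39 ± 0.22), Acsf2 (−1.32 ± 0.22), Donson (−1.22 ± 0.21), St6galnac2 (−1.17 ± 0.20) and Mrtfb (−1.14 ± 0.19). NZW lay close to CBA for Ctse (11.87 against 11.98) and for Syt14, and Balb for St6galnac2 (6.32 against 6.22). All 32 effector regulatory T-cell genes lay above 0 in CBA, with a median of 0.401. Of these, Crip1 rose (1.02 ± 0.18), none fell and 31 did not pass, while 6 rose adjusted over the list alone. The camera adjusted p was 3.55e-16 (adjusted p = 0.149 with an estimated correlation). The regulatory T-cell signature had a median of 0.265, no member that passed, 4 higher and 2 lower adjusted over the list alone, and a camera adjusted p of 6.47e-06 (adjusted p = 0.964 with an estimated correlation). The interferon-response list had a median of −0.181, no member that passed, 1 lower adjusted over the list alone, and a camera adjusted p of 2.19e-06 (adjusted p = 0.964 with an estimated correlation). The other 18 lists had camera adjusted p values of 0.162 to 0.981.

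In total, 37 genes differed in CBA, 21 higher and 16 lower, and 537 had an unadjusted p below 0.05. The count was 15 when the tissue-set arrays were left out of the fit, 97 without B6 replicate 2 and 155 without B6 replicate 1. Leaving out other strain-set arrays gave 24 (Balb replicate 1), 19 (Balb replicate 2), 23 (NOD replicate 1), 21 (NOD replicate 2), 19 (NZW replicate 1) and 20 (NZW replicate 2), and leaving out B6 replicate 2 and NOD replicate 1 together gave 95.

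In NOD spleen, Defa24, which encodes a defensin of Paneth cells, was 12.6-fold higher (3.66 ± 0.67, limma adjusted p = 0.0117), Anpep, a brush-border aminopeptidase, 10.8-fold (3.44 ± 0.64, limma adjusted p = 0.013) and Apoa1, an apolipoprotein of liver and intestine, 8.86-fold (3.15 ± 0.57, limma adjusted p = 0.0113). The mean of the other strains for Defa24 was 3.08, near the lowest hundredth of intensities on the arrays, so the size of its fold is uncertain. The 2 NOD arrays were far apart for these genes, with Apoa1 at 11.33 and 7.88, Anpep at 10.94 and 7.04, and Defa24 at 8.78 and 4.70. The mucin gene Muc3 (2.85 ± 0.26) and the goblet-cell lectin gene Zg16 (2.42 ± 0.42) were high on both NOD arrays, and Zg16 read 10.92 and 10.44. Falls included Cyp4f18 (4.01-fold lower, limma adjusted p = 4.13e-05), S100a11 (−1.41 ± 0.17) and Cd8b1 (−1.28 ± 0.15).

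Further rises in NOD were Lyz1, the lysozyme of Paneth cells (3.10 ± 0.68), Zfp979 (2.58 ± 0.32), Car4, a carbonic anhydrase (2.58 ± 0.32), Aoc1 (2.56 ± 0.34), Fabp2, the intestinal fatty-acid binding protein (2.54 ± 0.38), and Il18r1 (1.25 ± 0.16). Further falls were D17H6S56E-5 (−1.78 ± 0.17), Desi1 (−1.58 ± 0.14), the histone genes H4c4 (−1.49 ± 0.15) and H2ac4 (−1.41 ± 0.30), Trim12c (−1.44 ± 0.18), Ifitm3 (−1.38 ± 0.17), Pagr1a (−1.31 ± 0.19) and Eif2ak2, which encodes the kinase PKR (−1.31 ± 0.18). The mean of the other strains for Ifitm3 includes the high NZW value (10.91), and NOD stood at 7.44 against 7.81 in B6, 7.90 in Balb and 8.65 in CBA. B6 was nearly as low for Cyp4f18 (5.90 against 5.46 in NOD), CBA nearly as high for Zfp979 (6.96 against 7.66) and NZW for Il18r1 (9.01 against 9.24). Without NOD replicate 1 the differences shrank to 1.62 for Defa24, 1.49 for Anpep, 1.42 for Apoa1, 1.61 for Aoc1 and 1.51 for Fabp2, which still passed, while that of Car4 grew. Lyz1 no longer passed without NOD replicate 1 (1.04, limma adjusted p = 0.182), nor did Zg16 (2.18, limma adjusted p = 0.202). Capg (−1.18 ± 0.20), Actn1 (−1.15 ± 0.13), H2-T24 (−0.92 ± 0.17), Nsg2 (−0.77 ± 0.16), Cd101 (−0.71 ± 0.14) and Gpr183 (−0.55 ± 0.13) also fell, and the integrin gene Itgb1 rose (0.67 ± 0.15). Nsg2 was lower still in Balb (6.03 against 7.30).

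The interferon-response list lay lower in NOD. Of 40 members, none rose, 3 fell, namely Rtp4 (1.996-fold lower), Usp18 (−0.85 ± 0.19) and Oasl2 (−0.71 ± 0.14), and 37 did not pass, with 11 lower adjusted over the list alone. Oasl2 was lower still in Balb, and the mean against which it was set includes the high NZW (8.62) and B6 (7.82) values. The median of the interferon-response list was −0.288 and its camera adjusted p 2.91e-09 (adjusted p = 0.838 with an estimated correlation). Of 32 cell-cycle genes, the mitotic genes Kif11 (−0.94 ± 0.18) and Nusap1 (−0.97 ± 0.21) fell and none rose, with 3 lower adjusted over the list alone, a median of −0.252 and a camera adjusted p of 6.17e-05 (adjusted p = 0.838 with an estimated correlation). Of 42 regulatory T-cell signature genes, Capg and Klrg1 (−0.93 ± 0.20) fell, with 10 lower adjusted over the list alone, a median of −0.186 (−0.115 after another quantile normalization) and a camera adjusted p of 0.00797 (adjusted p = 0.838 with an estimated correlation). Of 32 effector genes, Klrg1 fell and none rose, with 2 higher and 6 lower adjusted over the list alone, a median of −0.152 (−0.075 after another quantile normalization) and a camera adjusted p of 0.0399 (adjusted p = 0.838 with an estimated correlation). Of 5 myeloid markers, the lysozyme genes Lyz1 and Lyz2 (1.21 ± 0.26) rose, also when adjusted over the list alone, with a list median of 0.119 (0.064 after median centring) and a camera adjusted p of 0.0114 (adjusted p = 0.838 with an estimated correlation). Without NOD replicate 1, the array with the higher Apoa1 and Anpep, the myeloid list no longer passed, nor did Lyz2 (0.62, limma adjusted p = 0.733). The other 16 lists had camera adjusted p values of 0.16 to 0.942. Of the 5 lists that passed in NOD, 2 remained without B6 replicate 1, where the signature, effector and myeloid lists were lost, and 3 without NOD replicate 1, where the effector and myeloid lists were lost. The effector list was also lost without Balb replicate 2 or NZW strain-set replicate 2.

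In total, 202 genes differed in NOD, 97 higher and 105 lower, and 1123 had an unadjusted p below 0.05. The count was 60 without NOD replicate 1, 118 without NOD replicate 2, 134 without Balb replicate 2, 130 without NZW strain-set replicate 2, 395 without B6 replicate 1 and 404 without B6 replicate 2. With NOD replicate 1 and B6 replicate 2 both left out it was 154.

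The tissue comparison asked how NZW regulatory T cells of bone marrow differ from those of spleen. Bone marrow cells took 3 rounds of sorting and spleen cells 2, so tissue and sorting cannot be told apart in this comparison. Bone marrow replicate 2 came from mice of 8 weeks and the other arrays from mice of 9 weeks. Klrg1, an inhibitory receptor of differentiated lymphocytes, was 6.54-fold higher (2.71 ± 0.25, n = 2 against 2 arrays, limma adjusted p = 0.000197), the inhibitory receptor gene Tigit 4.26-fold (2.09 ± 0.20) and the chemokine receptor gene Cxcr3 3.55-fold (1.83 ± 0.16). Prdm1, which encodes Blimp-1, rose by 1.78 ± 0.23 and Il10 by 1.60 ± 0.18. Satb1 (−1.64 ± 0.18), Bcl2, which protects against apoptosis (−1.41 ± 0.18), and Bach2, a repressor of effector genes (−1.39 ± 0.20), fell. Foxp3 differed by 0.19 ± 0.22 and did not pass.

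**Figure D2:**
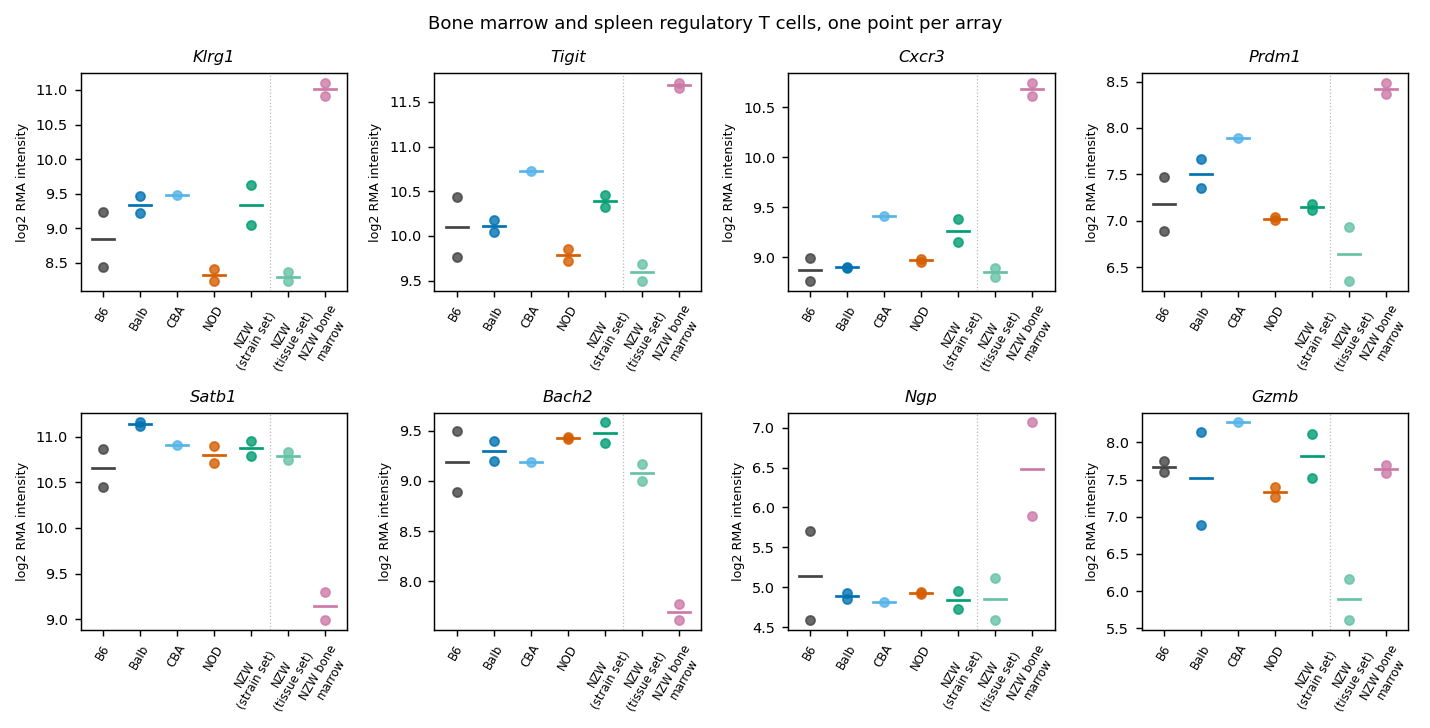
Log2 RMA intensity of 8 genes on each of the 13 arrays, with bone marrow at the right of each panel. Each point is 1 array and horizontal lines are group means. Klrg1 lies at 11.01 in bone marrow and 8.30 in tissue-set NZW spleen, Satb1 at 9.14 and 10.79, and Gzmb in bone marrow is near its level in strain-set NZW spleen.

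Of 32 effector genes, 21 rose in bone marrow, none fell and 11 did not pass, with 25 higher adjusted over the list alone. All 32 lay above 0, with a median of 1.028. The camera adjusted p was 1.23e-26, and this list also passed in the stricter test, with adjusted p = 0.044 with an estimated correlation. S100a4 (1.88 ± 0.18), Ccr2 (1.96 ± 0.25), Fgl2 (1.94 ± 0.23), Cxcr6 (1.27 ± 0.19), Itgae, the integrin CD103 (1.51 ± 0.20), and the transcription factor genes Tbx21 (1.15 ± 0.22) and Maf (1.08 ± 0.25) were among the members that rose. Against the strain-set NZW spleen arrays, a reference chosen after the data were seen, 13 effector genes rose, none fell and the median was 0.231, with a camera adjusted p of 6.26e-06. With that reference the differences were 1.68 for Klrg1, 1.29 for Tigit, 1.04 for Ccr2, 0.95 for S100a4 and 0.81 for Il10, and Itgae (0.58) and Tbx21 (0.29) no longer passed.

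Of 4 markers of neutrophils and marrow progenitors tested, 3 rose in bone marrow, namely Mmp9 (1.82 ± 0.21), Ngp (1.63 ± 0.37) and Lcn2 (1.26 ± 0.19), none fell, and 4 rose adjusted over the list alone. Ngp no longer passed without bone marrow replicate 1 (1.05, limma adjusted p = 0.141) or tissue-set spleen replicate 2 (limma adjusted p = 0.312). The median was 1.446 and the camera adjusted p 5.28e-06 (adjusted p = 0.0868 with an estimated correlation). The median member stood above the mean of all arrays by 1.545 and 0.889 on the 2 bone marrow arrays. Of 7 markers of NK, CD8 and γδ T cells, the chemokine gene Ccl5 rose (2.54 ± 0.24) and Eomes fell (−0.77 ± 0.16), with 2 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.142 (adjusted p = 0.471 with an estimated correlation). Among B-cell markers, Cd74 rose (1.42 ± 0.25), whereas H2-Aa fell (−1.40 ± 0.21). The B-cell marker list had 1 member higher and 1 lower, 2 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 0.102 (adjusted p = 0.471 with an estimated correlation). Against strain-set NZW spleen the B-cell list passed, with 2 higher, none lower, a median of 0.586 and a camera adjusted p of 0.000342.

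Of 17 resting-state genes, 7 fell in bone marrow, 1 rose (Il7r, 0.72 ± 0.18) and 9 did not pass, with 12 lower and 1 higher adjusted over the list alone. Foxp1 (−0.80 ± 0.16) fell with Satb1, Bcl2 and Bach2, the list median was −0.734 and the camera adjusted p was 1.9e-06 (adjusted p = 0.237 with an estimated correlation). Of 18 genes known to be low in regulatory T cells, 9 fell, 1 rose and 8 did not pass, with 14 lower and 1 higher adjusted over the list alone. Nsg2 (−1.35 ± 0.19) and Actn1 (−1.05 ± 0.16) were among those that fell, the median was −0.798, and the camera adjusted p was 7.95e-08 (adjusted p = 0.0697 with an estimated correlation). Of 42 signature genes high in regulatory T cells, 14 rose, 1 fell (Gpr83, −1.71 ± 0.21) and 27 did not pass, with 17 higher and 4 lower adjusted over the list alone. The median was 0.213 and the camera adjusted p 3.05e-07 (adjusted p = 0.471 with an estimated correlation). That median was 0.025 against strain-set NZW spleen, with 10 higher and 4 lower, 0.078 after median centring and 0.345 after another quantile normalization.

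Of 40 interferon-response genes, none rose in bone marrow, 8 fell and 32 did not pass, with 14 lower adjusted over the list alone, a median of −0.428 and a camera adjusted p of 8.89e-06 (adjusted p = 0.485 with an estimated correlation). Ifit1 (−1.16 ± 0.24), Usp18 (−1.06 ± 0.23), Slfn5 (−0.99 ± 0.21) and Rtp4 (−0.97 ± 0.18) fell. Of 29 trafficking receptors, 9 rose, 4 fell and 16 did not pass, with 9 higher and 6 lower adjusted over the list alone, a median of 0.158 and a camera adjusted p of 0.00378 (adjusted p = 0.485 with an estimated correlation). Of 32 cell-cycle genes, Ccnb2 (1.10 ± 0.26) and Ccna2 (1.12 ± 0.29) rose, also when adjusted over the list alone, with a median of 0.13 and a camera adjusted p of 0.0356 (adjusted p = 0.722 with an estimated correlation). Against strain-set NZW spleen the cell-cycle list turned, with 1 higher, 13 lower and a median of −0.571, and the trafficking list no longer passed, with 5 higher, 3 lower, a median of 0.056 and a camera adjusted p of 0.135. The trafficking call was also lost without tissue-set spleen replicate 1 (camera adjusted p = 0.119), and the cell-cycle call without that array or bone marrow replicate 2. After median centring the trafficking and cell-cycle medians were 0.045 and 0.018, and after another quantile normalization the interferon-response median was −0.253.

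Among lists that did not pass by camera (adjusted p of 0.0674 to 0.929), several had members that fell, and some depended on the reference. Against strain-set NZW spleen, the immediate-early and heat-shock list passed with 9 lower (camera adjusted p = 0.00085) and the list of Foxp3 regulation and stability with 13 lower and 1 higher (camera adjusted p = 0.000176). T-cell receptor signalling genes numbered 5 lower, none higher and 27 that did not pass of 32, with 2 higher and 6 lower adjusted over the list alone and adjusted p = 0.722 with an estimated correlation, and Themis (−1.12 ± 0.16) and Txk (−1.05 ± 0.19) fell. Of 31 immediate-early and heat-shock genes, 6 fell and none rose, which held adjusted over the list alone (adjusted p = 0.722 with an estimated correlation), including Hspd1 (−1.55 ± 0.27), Hspe1 (−1.29 ± 0.21), Egr1 (−1.12 ± 0.22) and Hsph1 (−0.97 ± 0.20). Of 20 apoptosis genes, 4 fell and none rose, which held adjusted over the list alone (adjusted p = 0.722 with an estimated correlation). These were Bcl2, Xiap (−1.10 ± 0.28), Cflar (−0.94 ± 0.24) and Bcl2l11 (−0.73 ± 0.18).

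**Figure D3:**
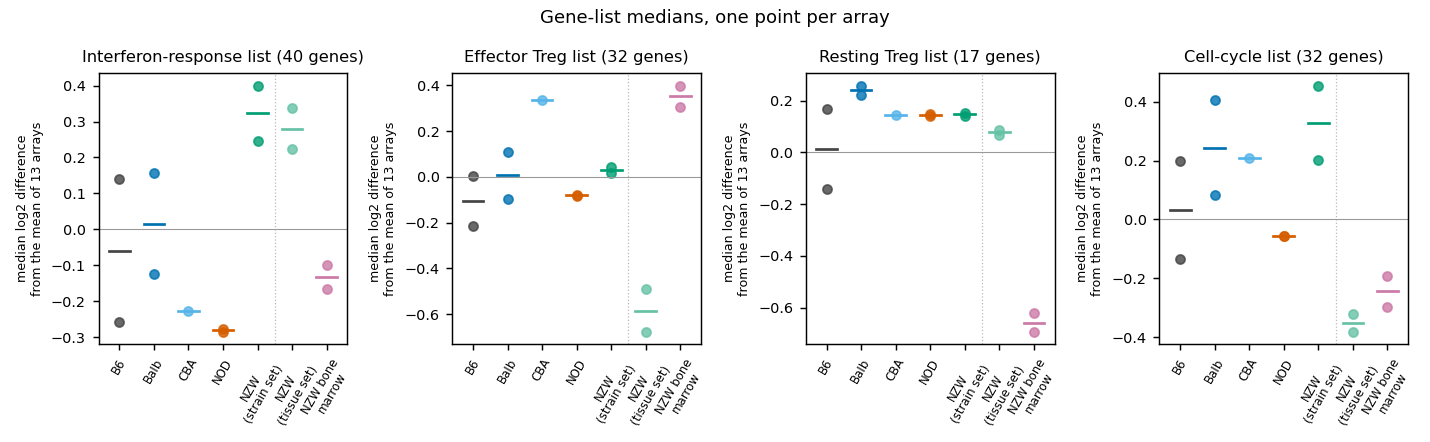
Median log2 difference of the members of 4 gene lists from the mean of all 13 arrays, with 1 point per array and horizontal lines at group means. The 2 strain-set NZW arrays lie at 0.400 and 0.247 on the interferon-response list, and the bone marrow arrays at 0.306 and 0.399 on the effector list against −0.678 and −0.492 in tissue-set spleen.

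Outside the lists, the largest rises in bone marrow were the potassium-channel gene Kcnma1 (2.75 ± 0.32), the chemokine gene Cxcl10 (1.90 ± 0.32), Pglyrp1 (2.36 ± 0.19) and Utf1 (1.93 ± 0.23). The largest falls were Ift80 (−1.81 ± 0.20), Myc, a driver of growth (−1.81 ± 0.16), Tnfsf8 (−1.72 ± 0.28), Klrb1f (−1.68 ± 0.19), Ifi214 (−1.66 ± 0.24), Ms4a4c (−1.65 ± 0.20), Klrb1b (−1.64 ± 0.17) and Rgs1 (−1.56 ± 0.17). Gzmb, which encodes granzyme B, rose by 1.76 ± 0.33. Klrb1b, Gzmb, Ccnb2, Ccna2 and H2-Aa changed sign when strain-set spleen was the reference, and Klrb1f (−0.05) and Lta (−0.29) no longer passed. The differences of Il7r (1.53) and Bcl2l11 (−1.36) were larger with that reference.

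In total, 728 genes differed between bone marrow and tissue-set spleen, 185 higher and 543 lower (25.4% higher), and 2935 had an unadjusted p below 0.05. The median of all genes was −0.0752. The bone marrow arrays had narrow intensity distributions, with log2 interquartile ranges of 2.438 and 2.343, near that of B6 replicate 2 (2.326). The tissue-set spleen arrays had 2.548 and 2.918. Another quantile normalization moved the split to 289 higher and 466 lower (38.3% higher), and centring each array on its median to 106 higher and 726 lower (12.7% higher) with a median of all genes of −0.198. The count was 41 without tissue-set spleen replicate 2, 75 without bone marrow replicate 2, 201 without bone marrow replicate 1 and 2065 without either B6 array. It was 391 without either Balb array, 380 without either NOD array and 459 without either strain-set NZW array.

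NZW spleen was measured in both sets, which gave the difference between the sets themselves. In the tissue set, Zg16 was 13-fold lower (−3.70 ± 0.52, n = 2 against 2 arrays, limma adjusted p = 0.00904), Ceacam1 10.7-fold lower (−3.43 ± 0.58) and Agr2, a protein of mucus-secreting cells, fell by 2.13 ± 0.40. Ceacam1 and Agr2 no longer passed when any of these 4 arrays was left out, and Zg16 passed only when that array was strain-set replicate 2. The cyclin gene Ccna2 fell by 2.35 ± 0.29 (limma adjusted p = 0.00403) and the proliferation marker Mki67 by 1.99 ± 0.29. Higher in the tissue set were Atp5md (1.97 ± 0.17), the C-type lectin genes Klrb1b (1.88 ± 0.17) and Klrb1f (1.63 ± 0.19), H2-Aa (1.65 ± 0.21) and Cnpy2 (1.12 ± 0.19).

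Of 32 cell-cycle genes, 9 fell in the tissue set, none rose and 23 did not pass, with 18 lower adjusted over the list alone. Ccnb2 (−1.94 ± 0.26), Nusap1 (−1.76 ± 0.26) and Kif11 (−1.65 ± 0.22) were among them, the median was −0.651 and the camera adjusted p 2.49e-24 (adjusted p = 0.111 with an estimated correlation). Of 32 effector genes, 3 fell, namely Gzmb (−1.93 ± 0.33), Anxa2 (−1.28 ± 0.23) and Crip1 (−1.14 ± 0.17), none rose and 29 did not pass, with 20 lower adjusted over the list alone. That list had a median of −0.611 and a camera adjusted p of 2.49e-24 (adjusted p = 0.0569 with an estimated correlation). Of 31 immediate-early and heat-shock genes, 3 fell, namely Jun (−1.36 ± 0.23), Fos (−1.24 ± 0.19) and Nr4a3 (−0.97 ± 0.16), with 5 lower adjusted over the list alone and a camera adjusted p of 7.9e-05 (adjusted p = 0.512 with an estimated correlation).

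Of 42 regulatory T-cell signature genes, 1 fell (Gzmb), with 6 lower adjusted over the list alone, a median of −0.323 and a camera adjusted p of 7.35e-07 (adjusted p = 0.512 with an estimated correlation). Of 40 genes of Foxp3 regulation and stability, 1 fell (Nr4a3), with 2 lower adjusted over the list alone, a median of −0.22 and a camera adjusted p of 3.08e-06 (adjusted p = 0.46 with an estimated correlation). No member passed among 14 helper T-cell genes (5 lower adjusted over the list alone, median −0.277, camera adjusted p 0.00141, adjusted p = 0.104 with an estimated correlation). The same held for 29 trafficking receptors (1 higher and 6 lower adjusted over the list alone, median −0.173, camera adjusted p 0.0135, adjusted p = 0.7 with an estimated correlation). The helper call was lost without tissue-set spleen replicate 2 and the trafficking call without tissue-set spleen replicate 1 (camera adjusted p = 0.384). Of 5 B-cell markers, H2-Aa rose, also when adjusted over the list alone, with a median of 0.414 (0.265 after median centring) and a camera adjusted p of 0.000652 (adjusted p = 0.114 with an estimated correlation). The interferon-response list, with a median of −0.007 and no member past the test, gave a camera adjusted p of 0.686 (adjusted p = 0.908 with an estimated correlation).

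In total, 36 genes differed between the sets, 6 higher and 30 lower, and 911 had an unadjusted p below 0.05. The count was 258 when the 4 NZW spleen arrays were fitted alone, 11 and 6 without strain-set NZW replicate 1 or 2, 6 and 4 without tissue-set spleen replicate 1 or 2, and 164 without either B6 array.

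A few lists passed the camera test in none of the 7 comparisons. Targets of interleukin-2 and STAT5 (16 genes) had adjusted p values of 0.206 to 0.937, genes of the MHC region (19) 0.153 to 0.981 and coinhibitory receptors (14) 0.339 to 0.929. Markers of plasma cells (4) had 0.221 to 0.994, of erythroid cells and platelets (5) 0.102 to 0.781 and of NK, CD8 and γδ T cells (7) 0.0865 to 0.94. In bone marrow, Prdm1 and Gzmb rose and Bcl2 and Lta (−0.77 ± 0.17) fell among the targets of interleukin-2 and STAT5. Tigit rose and Cd200 (−0.90 ± 0.17) and Btla (−0.82 ± 0.18) fell among coinhibitory receptors, and H2-Aa and H2-T24 (−0.75 ± 0.21) fell in the MHC region. Of the T-cell receptor beta segments, 1 member was tested and it passed in no comparison.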

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

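The tests of the goblet genes' strain regulation, of the goblet list in bone marrow, of B6 replicate 2 and of the interferon-response list, including the one with unshared references, were chosen only after the result was seen. The other tests of the intestinal genes were written before they were run.

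Of the 140 genes that passed in NZW against the other 4 strains, 5 also differed between strain-set and tissue-set NZW spleen. They are among the 36 genes that differed between the sets, since the limma contrast is the same. Akr1c18 stood 2.84 above the other strains in the strain set and 0.74 in the tissue set, a difference of −2.11 ± 0.23 (SE, limma adjusted p = 0.00178). Anxa2 stood at 0.88 and −0.40, a difference of −1.28 ± 0.23 (limma adjusted p = 0.0358). Arhgap20 stood at −1.29 and −2.30, a difference of −1.01 ± 0.18 (limma adjusted p = 0.0312). Klrb1f stood at −1.88 and −0.25, a difference of 1.63 ± 0.19 (limma adjusted p = 0.00307). Lgmn stood at 1.16 and −0.20, a difference of −1.36 ± 0.20 (limma adjusted p = 0.0102).

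Intestinal transcripts were high in NOD spleen, and RNA of enterocytes and Paneth cells on NOD replicate 1 could account for part of them. That account does not extend to Muc3, which was alike on both NOD arrays (SD 0.144), or to Car4, whose difference grew without NOD replicate 1. Over a second list of such genes (33 measured, 13 of them above the expression filter), NOD replicate 1 lay above the mean of the 7 non-NOD arrays by a median of 1.25, with 31 genes above 0, and NOD replicate 2 by 0.1, with 23 above 0. Regulation by strain alone is unlikely, since the median gap between the 2 NOD arrays was 1.09, and the abundant intestinal genes Apoa1 and Apoa4, outside that list, read 11.33 and 10.15 on NOD replicate 1 against 7.88 and 6.88 on replicate 2. On 9 strain-set arrays a second goblet-cell list of 33 genes followed Zg16, with Spearman rho of 0.85 (permutation p = 0.0059). The Pearson r was 0.88 (permutation p = 0.0016), or 0.84 without the 2 farthest arrays. B6 replicate 2, with the narrowest intensity distribution of the strain set (interquartile range 2.326), had a goblet median of 0.208. Its enterocyte and Paneth median was 0.336. Balb replicate 2, with the widest distribution (3.073), had the lowest goblet median, −0.182. These lists were not filtered for expression, and the permutation p does not account for such differences between arrays. The bone marrow arrays, lowest in Zg16 (4.56 and 4.72), had list medians of 0.146 and 0.212, as high as NOD (0.138 and 0.212). They stood about as high on the enterocyte and Paneth list (0.125 and 0.202), so their goblet medians cannot decide the question. Tissue-set NZW spleen, nearly as low in Zg16 (4.79 and 4.96), had goblet medians of 0.063 and −0.16. Goblet-cell RNA and strain regulation of the goblet genes in NOD both stay open. Zg16 differed by 1.62 between the strain-set NZW arrays and by 1.58 between the Balb arrays. Zg16 read 9.38 and 7.76 on strain-set NZW spleen, far above tissue-set NZW spleen, and Muc2, Ceacam1 and Agr2 were also higher there. Strain alone would therefore not set the level of these genes. The sort for CD4 T cells would remove epithelial cells.

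B6 replicate 2 lay far from all other arrays, and 3 technical accounts were tested. Of the genes that separate B6 replicate 1 from the other strains by 2-fold, 49 of 65 (75.4%) placed it nearer to B6 replicate 1, which left the question open. A 4-fold threshold, chosen after that result, gave 12 of 13 (92.3%), so another strain is unlikely. After quantile normalization the SD between the B6 replicates was 0.5, against 0.32 for the widest other pair, so scaling alone would not account for it. Over 6 marker lists the highest percentile among 10000 random gene sets was 89.8, so RNA of these other cell types was not detected, and the cause may lie elsewhere.

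Interferon-response genes were higher in NZW spleen, a call that was lost with an estimated correlation (adjusted p = 0.433). A change of the Ifitm genes alone is unlikely, since the list holds none of them, Oasl2, Oas2 and Rsad2 passed, and 92.5% of the list lay above 0 in the tissue-set arrays (median 0.398), which were set against the same reference arrays. With references that the sets did not share, the smaller median in the tissue set was 0.264 (35 of 40 genes above 0), where a batch effect of the strain-set NZW arrays would have left it near 0. Low values on B6 replicate 2 could not account for the pattern, since the median without it was 0.44. The NZW bone marrow arrays lay at −0.1 and −0.167 on this list, no marrow of another strain was measured, and joint movement of correlated genes, strain and exposure stay open.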

How the results depend on the processing

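The alternatives gave 6750 values for 272 pairs of a named gene and a comparison, with some genes named in several comparisons. Of these values, 6079 stayed on the same side of the threshold, 649 kept direction but no longer passed, 16 newly passed and 6 reversed. Direction was checked only where the gene passed in the main fit or in the alternative. The reversals were in bone marrow: Klrb1b 0.24, Gzmb −0.17, Ccnb2 −0.84, Ccna2 −1.22 and H2-Aa 0.24 with strain-set spleen as the reference, and Ccna2 −0.049 with the 4 spleen arrays pooled. With array weights the counts were 260 (NZW), 26 (B6), 272 (Balb), 106 (CBA), 589 (NOD), 74 (sets) and 825 (F test). With 1 set only they were 94 (B6), 15 (CBA), 112 (NOD), 1232 (bone marrow) and 258 (sets). Pooling the 4 NZW spleen arrays gave 303 (NZW) and 1756 (bone marrow), and strain-set spleen as the reference, chosen after the data were seen, gave 1512. Without B6 replicate 2 and NOD replicate 1, also chosen after, counts were 225 (NZW), 150 (Balb) and 95 (CBA). Balb had 130 with all probe sets and bone marrow 292 with no filter. With an estimated correlation, lists that passed numbered 0 (NZW, from 4), 0 (Balb, from 2), 0 (CBA, from 3), 0 (NOD, from 5), 1 (bone marrow, from 8) and 0 (sets, from 8), and with no filter 8 (B6, from 0), 11 (Balb) and 14 (bone marrow). The cause was not tested.

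Leaving out 1 array gave 50 to 330 (NZW), 95 to 3513 (B6), 28 to 482 (Balb), 19 to 155 (CBA), 60 to 404 (NOD), 41 to 2065 (bone marrow), 4 to 164 (sets) and 209 to 2665 (F test). Lists numbered 3 to 4 (NZW), 0 to 6 (B6), 2 to 4 (Balb), 3 to 4 (CBA), 2 to 6 (NOD), 7 to 9 (bone marrow) and 7 to 10 (sets), and the share with the same sign 93.9 to 100%. Leaving out either B6 array removes the spread of that pair from the pooled variance, and a group left with 1 array is assumed to vary like the others. Leaving out the lone CBA array gives no value for CBA. With the replicate number as a block, counts were 129 (NZW), 122 (B6), 75 (Balb), 16 (CBA), 193 (NOD), 515 (bone marrow), 47 (sets) and 280 (F test). Deviations of same-numbered arrays correlated from −0.335 to 0.401 over 15 pairs of groups, with 5 above 0.1 and 6 below −0.1. No pairing common to all groups was seen. Such correlations cannot exclude that same-numbered arrays of some groups were processed together.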

Other observations

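Several strain differences formed patterns that no comparison of 1 strain with the rest describes, and the genes in this paragraph were chosen after their values were seen. Nlrp1a, an inflammasome sensor, stood at 6.97 in NOD and 6.85 in NZW and at 4.72 or less in the other strains (limma adjusted p = 3.41e-05 in the F test). Ctse stood at 9.46 in B6 and 9.32 in NOD against 11.81 in Balb, 11.98 in CBA and 11.87 in NZW (limma adjusted p = 8.53e-06). Cd72 stood at 5.44 in CBA and 5.83 in NOD against 7.52 in Balb, 7.87 in B6 and 8.05 in NZW (limma adjusted p = 0.000124). Cyp4f18 stood at 5.46 in NOD and 5.90 in B6 against 7.33 in Balb, 8.16 in CBA and 8.46 in NZW (limma adjusted p = 2.21e-06).

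A hypothesis of this re-analysis, with its prediction written before the test, was that genes that differ among strains could lie next to each other in the genome. Of 307 such genes, 73 had another among the 2 tested genes on either side, against a median of 32 and an upper limit of the central range of 47 in 10000 random draws of 11233 placed genes. These include families such as Trim12a, Trim12c and Trim30d, or Ifitm1, Ifitm2 and Ifitm3. With neighbours of the same symbol stem left out, after a correction of the stem rule that followed a first result, the number was 46, against a median of 31 and an upper limit of 46 (permutation p = 0.03). The number lay at that limit and not above it, so the prediction was not met, and the data may neither establish nor exclude such neighbourhoods outside gene families.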
